A study of Homo sapiens with 2 samples.

How the data were processed

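Expression was measured in EOL-1 cells, a human eosinophilic leukaemia line that carries the FIP1L1-PDGFRA fusion kinase. Total RNA from 1 culture given 100 nM Glivec (imatinib, an inhibitor of ABL, KIT and PDGF receptor kinases) for 4 h and from 1 untreated culture was labelled with biotin and hybridised to Affymetrix arrays, per the labels. There were 2 arrays, 1 per group. With 1 array per group no difference has a replicate check, no test between groups was run and no p-value is given. The number of arrays limits the precision of every value.

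The deposited values are signal intensities on a linear scale, 1 per probe set. They were made with MAS5, per the submitters' processing notes, and the version is not given in the sources used here. The mean after removal of the lowest and highest 2% of signals was 100.014 on both deposited arrays, so the intensities had been scaled to a common level before deposit. No detection calls were used here. Each array holds 54675 probe sets, of which 62 are manufacturer's controls.

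Probe sets were named from the platform's annotation table, which can be old. It listed 42898 probe sets, of which 41097 had 1 gene symbol and 1801 had several. The other 11777 probe sets, controls included, are unnamed here, and no gene was named from a probe set with several symbols. Entrez identifiers matched 41043 probe sets to the NCBI gene table of assembly GRCh38.p14, which changed 0 symbols and was used for names alone. No genome build goes with the signals, so no coordinates are given.

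A floor was set at the median of all non-control signals on both arrays, a signal of 13.7, and lower signals were raised to it before log2 was taken. The floor is a chosen bound and not a measured background. A gene was represented by its probe set of highest mean signal over both arrays, on the linear scale before the floor. Probe sets whose suffix marks cross-hybridisation (_x_at) were used only where no other was present. The gene counted as measured with at least 1 array above the floor. Of 19775 annotated genes, 12705 were measured and 10975 were above the floor on both arrays. Ratios are Glivec over untreated. Where 1 array was at the floor the ratio is a bound, written "at least N-fold". A 2-fold difference, a log2 ratio of 1 in size, was the threshold for counts.

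Gene lists (29, with 633 entries, of which 574 had a probe set of 1 gene and 507 were measured) were chosen for signalling, metabolism, cell cycle, survival and blood lineages. The other entries are not analysed here. For each list the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A list is said to stand apart when its median lay outside the central 95% of them. This describes these 2 arrays and is no test between conditions. By chance 0.725 of 29 lists would lie outside in each direction, and lists share members.

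Named genes were the 12 largest and the 12 smallest ratios with both arrays above the floor, a difference of at least 2-fold and no probe set of opposite sign. To these were added the 4 largest bounds in each direction, 10 genes fixed in advance (PDGFRA, FIP1L1, CHIC2, FOXO1, FOXO3, FOXO4, MYC, DUSP6, CISH and PIM1), and up to 4 members of each list with the largest ratios in size. The lists, this rule, the floor, the threshold and all alternatives but 1 were fixed before the data were examined.

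The only available measure of error was the spread between probe sets of a gene, which leaves out all variation between cultures. Its pooled SD was 0.325 on the log2 scale over 5603 genes with several probe sets above the floor, from 0.438 in the dimmest of 4 equal signal classes to 0.228 in the brightest. Resampling these deviations around ratios of 0, in 100 runs, gave a mean of 70.1 genes at least 2-fold higher and 68.4 lower.

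The calculation was tested on simulated signals for 12253 genes in the Glivec and untreated comparison. Genes simulated as 3-fold different passed the threshold in 88% of cases in either direction (25 genes each). Genes simulated as 2-fold different passed in 64% when higher and 40% when lower, and those simulated as 4-fold different in 100% and 72%. Changed genes were drawn from those above the floor on the untreated array, so the floor limited mainly the simulated decreases. Increases from the floor, as in 96 of the genes found higher, were not simulated. Of 12028 genes simulated without a difference, 104 (0.865%) passed.

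Alternatives were quantile normalization, median centring, a loess trend on mean signal (span 0.3), floors at the 40th, 60th and 75th percentile, no floor with a pseudocount of 1.08, the mean over a gene's probe sets, only probe sets without _s_at, _x_at or _a_at suffix, and thresholds of 1.5-fold and 3-fold. Scaling to the hybridisation spike-ins was chosen after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 for the plots.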

Results

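EOL-1 cells depend on FIP1L1-PDGFRA, a fusion of the PDGF receptor alpha kinase that imatinib inhibits. The comparison asked which transcripts differed after 4 h with 100 nM Glivec, from 1 treated and 1 untreated culture on 1 array each. The signal exceeded the floor of 13.7 at 28078 probe sets (51.4%) on the Glivec array and 26603 (48.7%) on the untreated array. Over 24832 probe sets above it on both arrays the log2 signals correlated with r = 0.968 and rho = 0.961, across probe sets, which are not independent replicates.

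CD69, an early activation marker, was 11.1-fold lower on the Glivec array, with a signal of 42.6 against 474.5. The chemokine gene CXCL10 was 9.09-fold lower, the vasodilator peptide gene ADM 8.23-fold, the kinase gene PIM1 8.06-fold and MYC 6.78-fold, with MYC signals of 557 and 3781. CISH, STON1, DUSP6, EGR1, TRIM16, MARS2 and CCR6 were 5.28-fold to 6.80-fold lower. CCL2, CCL8, AEN and TMEM201 were at the floor with Glivec and at least 12.2-fold, 12.2-fold, 8.91-fold and 7.48-fold lower, and another TMEM201 probe set was at -0.37. In the other direction SESN3, a stress-response gene of the sestrin family, was 6.08-fold higher and the arrestin-domain gene ARRDC3 5.51-fold. The other SESN3 probe sets with an array above the floor gave bounds, with log2 ratios of 0.07 to 1.32. YPEL4 was 5.46-fold higher, the noncoding AFTPH-DT 5.07-fold and CCNG2, which encodes cyclin G2, 4.43-fold, with signals of 4076 and 921. RNA45SN5, KLC4, TENT5B, ZNF76, BORCS6, CDKN1C and PAQR8 were 3.67-fold to 4.02-fold higher. LOC389199, DIRAS1, GEM and COX6A2 were at the floor in untreated cells and at least 5.56-fold, 4.59-fold, 3.98-fold and 3.92-fold higher. Several of these genes rest on 1 probe set, among them CD69, PIM1, MYC and ARRDC3.

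**Figure D1:**
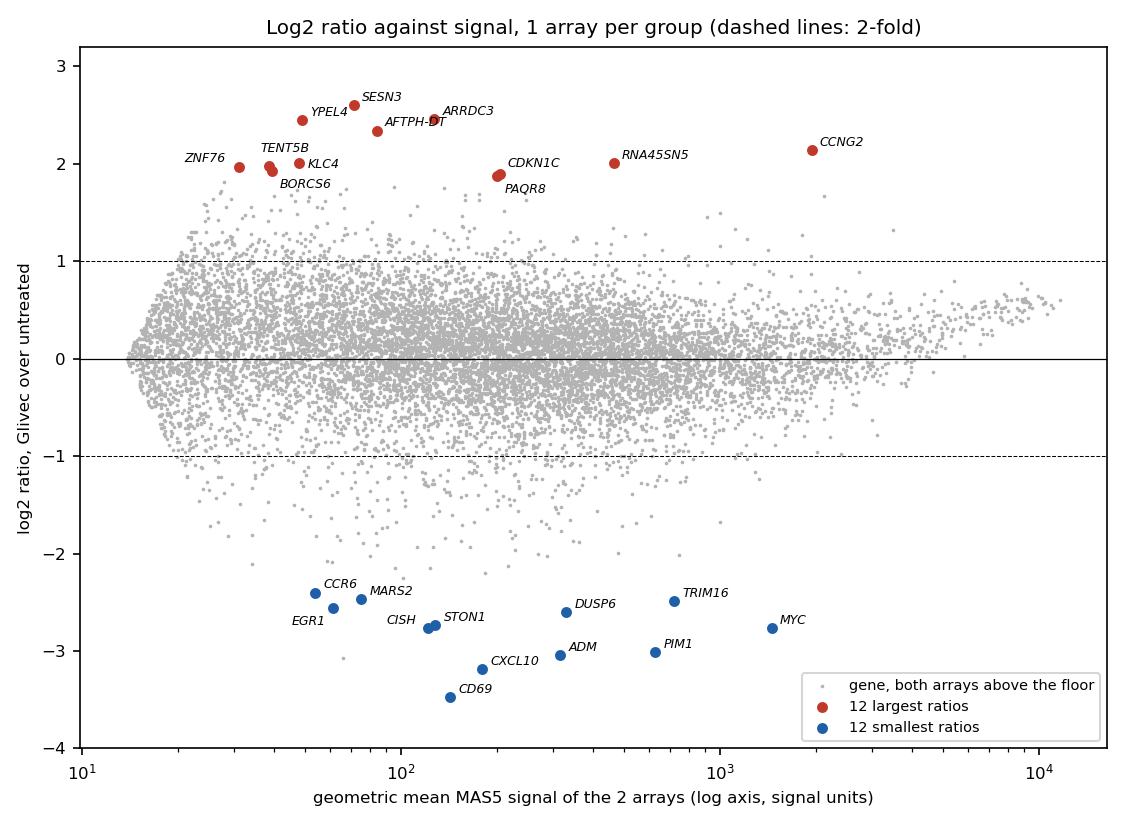
Each point is 1 of 10975 genes above the floor on both arrays, with the mean signal on a log axis and the log2 ratio of Glivec over untreated on the other. Coloured points are the 12 largest and 12 smallest ratios among genes with no probe set of opposite sign, from SESN3 at 2.60 to CD69 at -3.48. SOCS1, at -3.08, was left out by this rule. The brightest genes lie above 0.

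**Figure D2:**
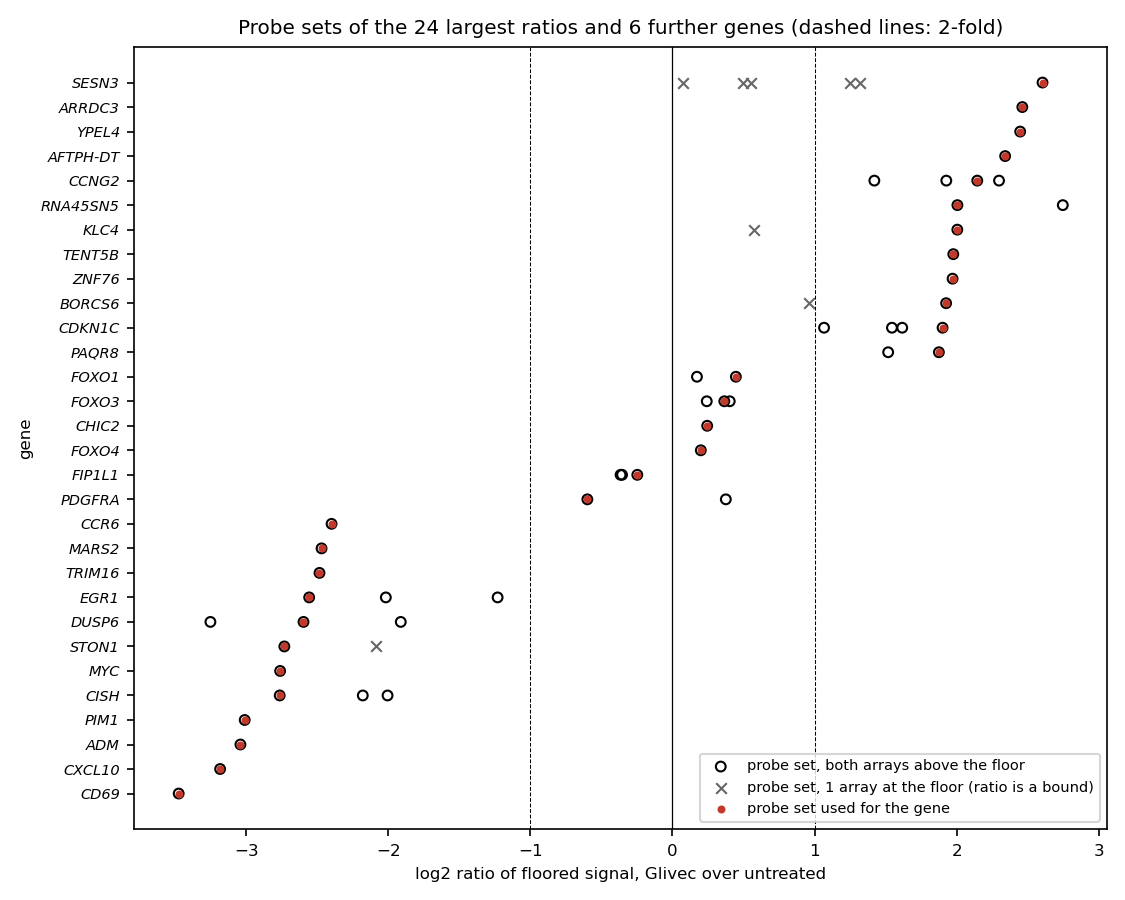
Log2 ratios of the separate probe sets of 24 genes and of PDGFRA, FIP1L1, CHIC2, FOXO1, FOXO3 and FOXO4, where crosses are bounds and filled points mark the probe set used. The 24 have the largest ratios among genes with no probe set of opposite sign, so their probe sets lie on 1 side of 0 by selection. The 4 CCNG2 probe sets lie between 1.42 and 2.30. The PDGFRA probe sets lie on opposite sides of 0, the positive one from dim signals (31.3 with Glivec against 24.1).

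Of 12705 measured genes, 398 (3.13%) were at least 2-fold higher with Glivec and 334 (2.63%) at least 2-fold lower, with 96 and 48 of these known as bounds. The remaining 94.2% lay within 2-fold. Spread between probe sets alone gave 49 to 93 higher and 48 to 86 lower genes in 100 simulated runs. Of 177 higher genes with several probe sets above the floor, 142 had all of them higher, and of 174 such lower genes 141 had all of them lower. The share of higher genes, 54.4%, depended on scaling: it was 42.2% with quantile normalization (290 higher, 398 lower), 37.8% with median centring (272 and 448), 34.3% after loess (234 and 449) and 1.7% with spike-in scaling (43 and 2484). It also depended on the floor, at 56.8% with no floor (2204 and 1678), 61.6% with the 40th percentile (735 and 459), 45.9% with the 60th (234 and 276) and 34.1% with the 75th (91 and 176).

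Control features differed between the arrays too. The 18 hybridisation spike-in probe sets, which the standard protocol adds in equal amount, had a median log2 ratio of 0.74 (0.42 to 0.89), or 1.67-fold higher on the Glivec array. Scaling to them moved the median of all genes from 0.10 to -0.59, so all differences here are relative to the bulk of genes. The 100 brightest genes included 44 ribosomal protein genes with a median log2 ratio of 0.55 and 56 others with 0.44. The 3' over 5' signal ratios were 1.04 with Glivec and 0.925 without for GAPDH, and 1.23 and 1.17 for ACTB.

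**Figure D3:**
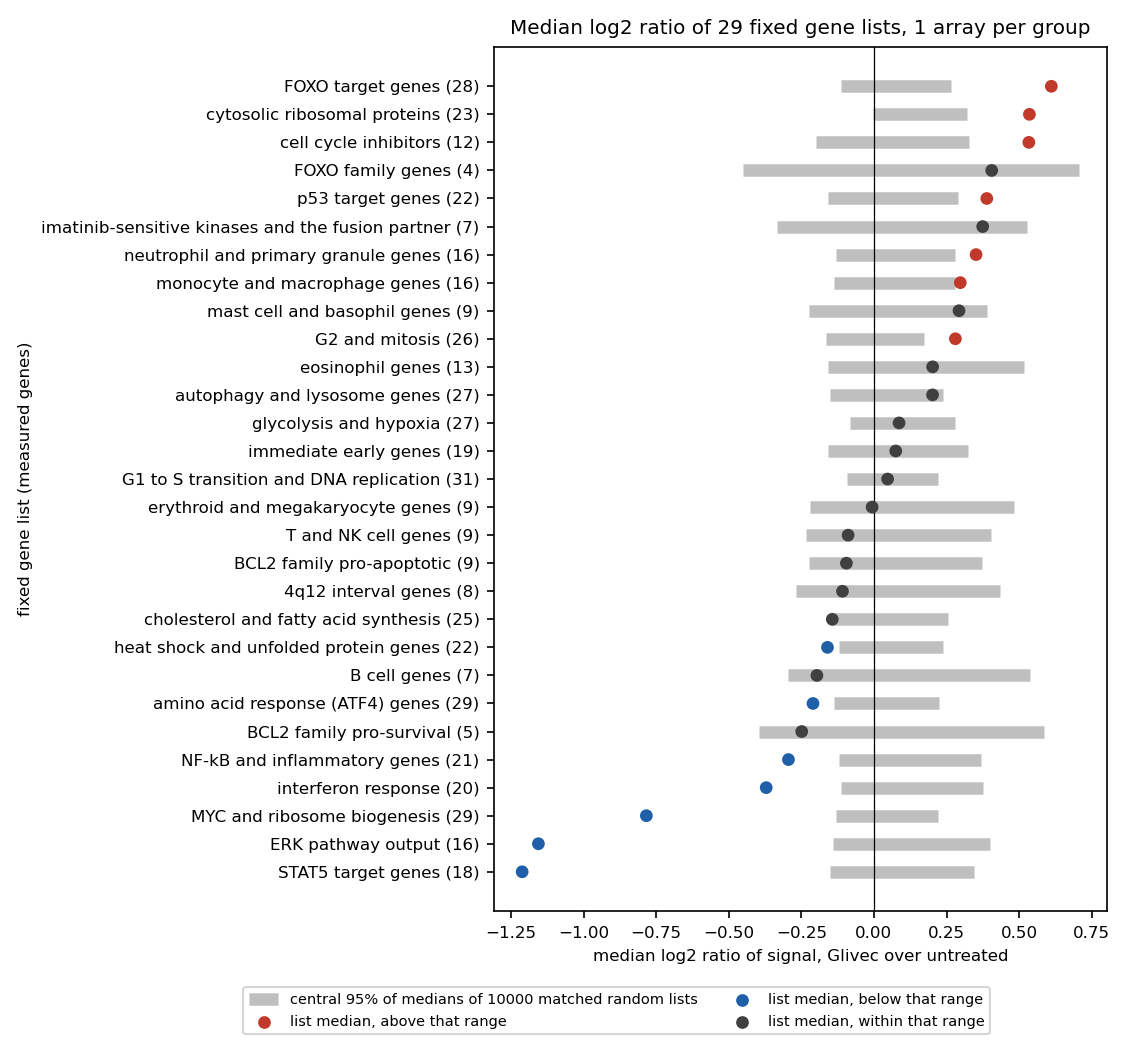
Median log2 ratio of each of 29 gene lists (points, number of measured genes in brackets) with the central 95% of medians of 10000 matched random lists (bars). STAT5 targets at -1.21 and ERK output at -1.16 lie farthest below and FOXO targets at 0.61 farthest above, and all 7 medians above the bars turn negative with spike-in scaling.

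Genes used as readouts of the ERK pathway were lower with Glivec as a list. Their median log2 ratio over 16 measured members was -1.16, below all 10000 random lists, with 9 members at least 2-fold lower and 0 higher. DUSP6, a phosphatase that acts on ERK, was 6.05-fold lower with 3 probe sets between -3.25 and -1.91, and the transcription factor gene EGR1 was 5.89-fold lower. FOSL1, of the AP-1 family, was at least 3.86-fold lower. The immediate early list as a whole did not stand apart, with a median of 0.08, a mean of -0.29 and a percentile of 41.5 over 19 genes. Its 4 members at least 2-fold lower were MYC, EGR1, FOSL1 and DUSP2 (2.34-fold).

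STAT5 target genes were the list with the lowest median, -1.21 over 18 genes and below all random lists, with 11 genes at least 2-fold lower and 1 higher. This rank depended on the processing. ERK output had the lower median with quantile normalization (-1.34 against -1.26), the mean over probe sets, only _at probe sets and spike-in scaling. STAT5 targets kept the lower median with median centring, loess, the other floors and the pseudocount. The cytokine-signalling inhibitors CISH, SOCS1 and SOCS2 were 6.80-fold, 8.44-fold and 3.29-fold lower. All 3 CISH probe sets were lower (-2.76 to -2.01). Another SOCS1 probe set had a log2 ratio of 0.36 from signals near the floor (22.1 with Glivec against 17.2). A further SOCS1 probe set, at the floor with Glivec, was lower (4.74 against 44.6). For 6 members 1 array was at the floor.

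MYC targets of ribosome biogenesis were lower in 25 of 29 measured genes, with a median of -0.78, below all random lists, and 9 genes at least 2-fold lower. NIP7 was 4.03-fold lower, the polymerase subunit gene POLR1C 3.41-fold and NOP16 3.05-fold, with BYSL at a log2 ratio of -1.58. Another NOP16 probe set, at the floor in untreated cells, was higher with Glivec (25.8 against 9.55), and 2 more were at -2.04 and -0.68. Cytosolic ribosomal protein genes went the other way by a small amount: 22 of 23 were positive and the median was 0.54, above all random lists, but -0.014 with quantile normalization and -0.20 with spike-in scaling. RPL37, RPS14, RPL30 and RPL27 were each 1.53-fold to 1.54-fold higher, and 2 dim RPS14 probe sets were at -0.60 and -0.43. Quantile normalization put the list at percentile 45.7, so that it no longer stood apart.

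FOXO target genes were higher in 25 of 28 measured members, with a median of 0.61, above all random lists, although it was -0.13 with spike-in scaling. The 8 at least 2-fold higher included SESN3, CCNG2 and KLHL24 (3.25-fold, with 4 other probe sets at 0.22 to 1.49), and the ubiquitin ligase gene FBXO32 was at least 5.11-fold higher. All 5 FBXO32 probe sets with an array above the floor gave bounds, and 1 of them was lower with Glivec (7.04 against 19.0). The FOXO transcription factor genes had a median of 0.41 over 4 genes, at percentile 82.4, with FOXO1 at 0.45, FOXO3 at 0.37, FOXO4 at 0.20 and FOXO6 at least 3.75-fold higher by a cross-hybridising probe set. Cell cycle inhibitors were positive in 12 of 12 genes, with a median of 0.53 (percentile 99.99), or -0.20 with spike-in scaling. Beside CCNG2, the CDK inhibitor gene CDKN1C was 3.74-fold higher with 4 probe sets between 1.07 and 1.90, the antiproliferative gene BTG1 had a log2 ratio of 1.32 (0.75 and 1.43 by others) and CDKN2D was 1.99-fold higher.

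Genes of G2 and mitosis were positive in 23 of 26, with a median of 0.28 (percentile 99.9), or -0.46 with spike-in scaling. The phosphatase gene CDC25C had a log2 ratio of 1.68, or 0.64 by another probe set, and HMMR was 2.04-fold higher, or at 0.90 by another. KIF20A was at 0.74, and AURKB at 0.67 by 1 probe set and -0.35 by another with signals near the floor (14.1 with Glivec against 17.9). For G1 to S and replication genes the median was 0.05, the mean -0.07 and the percentile 37.6 over 31 genes. CDC25A, a phosphatase that activates CDKs, was 3.46-fold lower, or at -1.36 and -0.95 by other probe sets. The replication licensing gene CDT1 was 2.10-fold higher, or at 0.45 by another, with FEN1 at -0.77 and MCM10 at -0.76.

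Interferon response genes were negative in 15 of 20, with a median of -0.37, below all random lists. GBP1 was 4.59-fold and RSAD2 4.21-fold lower, whereas ISG20 and IRF7 had log2 ratios of 0.81 and 0.78. Inflammatory genes of the NF-kB list had a median of -0.29 over 21 genes (percentile 0.08), with 4 at least 2-fold lower and 2 higher. Apart from CD69 and CCL2, TNF was 3.33-fold lower and IL1A 2.11-fold higher from signals near the floor. The NF-kB list no longer stood apart with only _at probe sets, at percentile 15.8.

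Among pro-survival BCL2 genes, BCL2L1 was 2.40-fold lower by its brightest probe set and at -0.63 and -0.28 by 2 others, BCL2A1 had signals of 18.9 with Glivec and 37.8 without, BCL2L2 was at 0.40 and MCL1 at -0.25 with other probe sets up to 0.98. The list median was -0.25 over 5 genes, at percentile 9.09. The pro-apoptotic list had a median of -0.09 and a mean of 0.07 over 9 genes, at percentile 14.7, and in it BMF was 3.09-fold higher while BID and PMAIP1 were at -0.43 and -0.35. The p53 target genes were positive in 16 of 22, with a median of 0.39 (percentile 99.8), or -0.38 with spike-in scaling. TP53INP1 was 2.12-fold and SESN1 1.97-fold higher, whereas the nuclease gene AEN was at least 8.91-fold and TIGAR 3.27-fold lower.

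The amino acid response list of ATF4 had a median of -0.21 over 29 genes (percentile 0.3), with the transporters SLC7A1 and SLC7A5 2.96-fold and 2.62-fold lower, the pseudokinase gene TRIB3 2.40-fold (-0.55 by another probe set) and VEGFA 1.96-fold. It no longer stood apart with only _at probe sets, at percentile 5.13. Heat shock and unfolded protein genes had a median of -0.16 over 22 genes (percentile 0.8), with XBP1 4.05-fold, SDF2L1 3.81-fold and the chaperone gene HSPA5 1.75-fold lower. MANF, a secreted protein of the endoplasmic reticulum, had signals of 286.7 with Glivec and 572 without. Cholesterol and fatty acid synthesis had a median of -0.14 over 25 genes (percentile 2.83) and stood apart only with the mean over probe sets. In it SQLE and HMGCS1 were 2.43-fold and 2.10-fold lower, MSMO1 was at -0.92 and SREBF1 was 2.04-fold higher. Other probe sets of HMGCS1 and SREBF1 were at -0.74 and 0.43. Glycolysis and hypoxia genes had a median of 0.09, a mean of -0.09 and a percentile of 40.6 over 27 genes, and beside ADM the glucose transporter genes SLC2A3 and SLC2A1 were 2.09-fold and 1.66-fold lower, with BNIP3L at 0.57. Autophagy and lysosome genes had a median of 0.20 over 27 genes at percentile 94.5 and stood apart only with the floor at the 75th percentile (98.8). In it the kinase gene ULK1 was 2.78-fold higher, with ATG14 at 0.95, GABARAPL1 at 0.79 and FNIP1 at 0.81, or 0.26 and -0.16 by other FNIP1 probe sets.

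Of the blood lineage lists, neutrophil granule genes had a median of 0.35 over 16 genes (percentile 99.6), or -0.34 with spike-in scaling, with CXCR2 2.45-fold higher and the granule proteases AZU1 and PRTN3 at 0.73 and 0.58. With only _at probe sets this list was at percentile 92.8. Monocyte genes had a median of 0.30 over 16 genes (percentile 98.3), or -0.41 with spike-in scaling, with C1QA at 0.90, MS4A7 at 0.88 and IRF8 at 0.72. The monocyte list no longer stood apart under 6 alternatives, with percentiles from 57.8 to 96.2. Eosinophil genes had a median of 0.20 over 13 genes at percentile 52.0, with the transcription factor gene GATA2 at -1.14, -0.86 and 0.20 by its 3 probe sets, CSF2RB at -0.83 and the peroxidase gene EPX at least 1.99-fold higher. Mast cell and basophil genes had a median of 0.29 over 9 genes at percentile 86.8.

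Lists for other blood cells held few measured genes, and none of them stood apart. Erythroid and megakaryocyte genes had a median of -0.01 and a mean of 0.10 over 9 genes at percentile 20.3, with HBB at least 2.22-fold higher by 1 of 3 probe sets. T and NK cell genes had a median of -0.09 and a mean of 0.08 over 9 genes at percentile 11.95, with CCR7 3.25-fold higher from an untreated signal of 15.0 and IL7R at -0.62. B cell genes had a median of -0.20 and a mean of 0.02 over 7 genes at percentile 6.75, with CD79A at 0.66 and CD79B at -0.36.

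The kinases that imatinib inhibits and the fusion partner had a median of 0.37 over 7 genes, at percentile 87.8. PDGFRA was at -0.60 by its brighter probe set (398 with Glivec against 602). The other was dim (31.3 against 24.1) and at 0.38. FIP1L1 was between -0.37 and -0.25 by 3 probe sets. KIT was 2.26-fold higher at low signal (44.98 against 19.9), CSF1R was at 0.41, and ABL2 probe sets ranged from -0.86 to 0.80. The 4q12 interval, where FIP1L1 and PDGFRA lie, had a median of -0.11 over 8 genes at percentile 12.6, with CHIC2 at 0.24 and USP46 2.43-fold lower by 1 probe set and at -0.59 by another.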

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

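Scaling to the spike-ins was chosen after seeing the data; all other alternatives were planned. No paired analysis was possible because each group has 1 array, and leaving out a replicate was not possible for the same reason. Of 14 lists that stood apart, all 14 still did with floors at the 60th and 75th percentile. After loess 13 did, as with the 40th percentile floor, the pseudocount, the mean over probe sets and spike-in scaling. With quantile normalization 12 did, and 11 with only _at probe sets. Median centring also kept all 14, but it shifts every gene and random list alike, so this was fixed by construction. Spike-in scaling is nearly such a shift and checks little. Lists that came to stand apart were autophagy genes with the 75th percentile floor (98.82) and cholesterol synthesis with the mean over probe sets (2.4). Of 73 named genes past 2-fold, 71 were past it in the same direction with quantile normalization, 68 with centring, 69 after loess, 61 with the mean over probe sets and 59 with spike-in scaling; with the 75th percentile floor 41 of the 58 that had a value were. Centring, spike-in scaling, other floors and the pseudocount could not turn the sign of a 2-fold ratio. With quantile normalization and loess none of these 73 changed sign. Neither did any with the mean over probe sets or only _at probe sets, where it had a value. Those 2 settings could not turn the genes named for the largest ratios and bounds, whose probe sets had 1 sign by selection. Nor could they turn genes with 1 probe set above the floor. Signals near the floor limit what can be seen, since a ratio there is a bound. Where the construction does not show it, the cause was not tested. Below, a median is said to have moved when it differed by more than 1 SD of its matched random lists, and to have reversed when the list had stood apart and its sign turned; smaller shifts are left out, and some of them cross 0.

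After loess, 234 genes were higher. There the medians that moved were 0.17 for ribosomal proteins, -0.32 for the ATF4 list, -0.063 for glycolysis and hypoxia and -0.52 for interferon response. With the floor at the 40th percentile, 735 genes were higher. There the medians that moved were -0.94 for ERK pathway output and 0.37 for T and NK cell genes. With the floor at the 60th percentile, 234 genes were higher and 276 lower. There the median that moved by this measure was 0.081 for imatinib-sensitive kinases. With the floor at the 75th percentile, 91 genes were higher and 176 genes were lower. There the medians that moved were -0.17 for imatinib-sensitive kinases, -0.94 for ERK pathway output, -0.996 for STAT5 target genes, 0.50 for FOXO target genes, -0.34 for the ATF4 list, 0.41 for monocyte genes, -0.29 for T and NK cell genes and 0.12 for B cell genes. With no floor and a pseudocount, 2204 genes were higher and 1678 genes were lower. There the medians that moved were -1.01 for ERK pathway output, -1.40 for STAT5 target genes, 0.17 for monocyte genes, 0.60 for mast cell genes, 0.19 for erythroid genes, 0.42 for T and NK cell genes and 0.098 for 4q12 interval genes. With spike-in scaling, 43 genes were higher and 2484 genes were lower, and all 29 medians were negative, 15 of which had been positive. Of lists that had stood apart, those that reversed were -0.13 for FOXO target genes, -0.20 for ribosomal proteins, -0.46 for G2 and mitosis, -0.20 for cell cycle inhibitors, -0.38 for p53 target genes, -0.34 for neutrophil genes and -0.41 for monocyte genes. There the medians that moved were -0.36 for imatinib-sensitive kinases, -1.90 for ERK pathway output, -0.59 for immediate early genes, -1.86 for STAT5 target genes, -0.33 for FOXO family genes, -0.88 for cholesterol synthesis, -1.52 for ribosome biogenesis and -0.69 for G1 to S genes. Further medians were -0.95 for the ATF4 list, -0.65 for glycolysis and hypoxia, -0.96 for NF-kB genes, -1.03 for interferon response, -0.99 for pro-survival genes, -0.72 for pro-apoptotic genes, -0.54 for autophagy genes and -0.90 for heat shock genes. Further medians were -0.54 for eosinophil genes, -0.41 for mast cell genes, -0.60 for erythroid genes, -0.62 for T and NK cell genes, -0.65 for B cell genes and -0.54 for 4q12 interval genes. At 1.5-fold, 1710 genes were higher and 1058 genes were lower. At 3-fold, 56 genes were higher and 86 genes were lower. With quantile normalization the list that had stood apart and reversed was ribosomal proteins at -0.014. Glycolysis and hypoxia, which had not stood apart, also turned negative. There the medians that moved were -1.34 for ERK pathway output, -0.047 for glycolysis and hypoxia and -0.26 for T and NK cell genes. With median centring the medians that moved were -0.88 for ribosome biogenesis, 0.44 for ribosomal proteins, -0.050 for G1 to S genes, 0.18 for G2 and mitosis, -0.31 for the ATF4 list, -0.010 for glycolysis and hypoxia and -0.26 for heat shock genes. With the mean over probe sets the medians that moved were 0.092 for imatinib-sensitive kinases, -1.004 for ERK pathway output, 0.23 for immediate early genes, -0.80 for STAT5 target genes, 0.43 for ribosomal proteins and 0.11 for monocyte genes. With only _at probe sets the medians that moved were -0.35 for imatinib-sensitive kinases, 0.39 for ribosomal proteins, -0.017 for NF-kB genes, -0.33 for heat shock genes, 0.027 for eosinophil genes, 0.23 for neutrophil genes, 0.41 for monocyte genes and 0.18 for B cell genes.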

Other observations

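The tests of the yippee-like genes, of brightness, of RNA degradation, of polymerase subunits without shared members and the scan of symbol stems were chosen after the results were seen; those of mitochondrial ribosomal proteins, polymerase subunits, tRNA synthetases and histones were set before. All 5 yippee-like genes, YPEL1 to YPEL5, were higher on the Glivec array, with log2 ratios of 1.76, 1.75, 1.69, 2.45 and 0.76, and their median was 1.75, or 1.01 with spike-in scaling and 0.76 with the floor at the 75th percentile. YPEL3 belongs to the FOXO target list and YPEL4 is among the 12 largest ratios, while YPEL1, YPEL2 and YPEL5 were chosen after their values were seen. The median's percentile of 100.0 among matched random lists restates the ratios that drew attention to the family and does not test whether it responds as a group.

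Genes of mitochondrial translation and of stable RNA synthesis were tested as possible companions of the lower ribosome biogenesis genes. Mitochondrial ribosomal protein genes were negative in 56 of 75, with a small median of -0.19 (percentile 0.01). By symbol stem, MRPL genes were at percentile 0.02 (-0.22) and MRPS genes at 5.7 (-0.16), so the latter did not stand apart by themselves. RNA polymerase I and III subunits had a median of -0.76 over 16 genes (percentile 0.0) with 5 at least 2-fold lower. They share POLR1A, POLR1B and POLR1C with the ribosome biogenesis list, and POLR1B and POLR1C are among those 5. The 13 subunits outside that list had a median of -0.68, below all random lists, with 3 at least 2-fold lower. Polymerase II subunits had a median of -0.16 over 12 genes (percentile 4.99, and 0.34 to 7.34 across the other settings), so the contrast with them is not settled, and the difference itself was not tested. Cytosolic tRNA synthetases were negative in 15 of 17 with a median of -0.19, but at percentile 3.3 (2.43 to 6.45 across the other settings) they narrowly missed the bound set for a joint decrease. Mitochondrial ones were negative in 9 of 15 and missed it, at percentile 25.5. Among 195 symbol stems of at least 8 measured genes, 18 lay below the central 95% and 10 above, against 4.88 by chance each. The 5 of lowest percentile were UTP (-0.64), MRPL (-0.22), DDX (-0.26), EXOSC (-0.57) and RRP (-0.61). They partly restate the ribosome biogenesis list, which holds UTP4, UTP20, RRP9, RRP12, RRP1B and DDX21. The stems of highest percentile were RPL (0.52), RPS (0.49) and then ZSCAN (0.58).

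Cytosolic ribosomal proteins were higher (median -0.20 with spike-in scaling) while ribosome biogenesis genes were lower, and 4 looks at brightness as a technical explanation gave different answers. The planned loess correction left a median of 0.17 that still stood apart (percentile 99.44). A loess with span 0.3 may not follow a rise confined to the brightest genes. The median was 0.07 in the brightest of 10 equal classes of signal. Among the 100 brightest genes, the 56 other than ribosomal proteins had a median of 0.44. The loess remainder therefore does not show an excess beyond brightness. Against each member's 50 neighbours in signal, the list median of 0.54 was at percentile 99.59, above their central range of 0.36 to 0.53. Tried only after that result, 10 neighbours gave percentile 50.35 (range 0.49 to 0.58). Quantile normalization, like loess, was fixed before the data were examined, but it was brought to this question only afterwards. It gave percentile 45.66. With the 10 neighbours and with quantile normalization no excess was left. Neither set of neighbours holds ribosomal protein genes, but 79.8% of the 50 were dimmer than their member and 55.7% of the 10, while quantile normalization equalises the brightest signals by construction. Part of the difference may follow brightness, and how much stays open with 1 array per group.

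Ribosomal RNA probe sets were higher on the Glivec array, with a median log2 ratio of 0.87 over 7 (0.20 to 2.75), or 0.13 relative to the spike-ins, and the 2 highest, of RNA45SN5, were already known to be high. Lists from 50 neighbours in signal spanned -0.34 to 0.38, with the median at percentile 99.99. Without RNA45SN5, a test added afterwards, the other 5 had a median of 0.79 at percentile 99.95, with ratios from 0.20 to 1.18. Several of these probe sets target the same ribosomal RNA, yet each was treated as an independent member. The percentiles may therefore be too extreme, and they do not decide whether signal level is the cause. RNA degradation is not seen in the control genes, whose larger 3' over 5' difference was 1.12-fold. More carry-over of transcripts without a poly(A) tail may contribute. Replication-dependent histone genes, picked by symbol, had a median of 0.33 at percentile 98.0. This percentile ran from 86.76 to 99.53 across the other settings, and the median was -0.40 at percentile 91.49 with spike-in scaling. Several of these genes had signals near the floor, and whether their transcripts lacked a poly(A) tail in these cells was not measured. A difference in ribosomal RNA synthesis was not tested.

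The excess of higher over lower genes could come from a difference between the arrays that varies with signal, but no test here decides this. The share of higher genes was 54.4%, and 34.3% after a loess trend on signal was removed, yet median centring, which shifts all genes alike, already gave 37.8%. With genes in 10 equal classes of signal, the median log2 ratio was 0.09 in the dimmest class, 0.37 in the next, -0.01 in the class below the brightest and 0.07 in the brightest, with 0.51 in the 100 brightest genes. No biological explanation was tested for this pattern.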
